A study of Arabidopsis thaliana with 4 samples.

How the data were processed

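Genomic DNA of 15-day-old Arabidopsis thaliana seedlings of the accessions Col-0 and C24 was compared on 4 two-colour arrays of chromosome 4. Per the labels' protocols, DNA was extracted with a column kit, labelled directly with Cy3 and Cy5 and not amplified. There were 2 DNA pairs, I and II, and each pair was hybridised on 2 arrays with the dyes exchanged. On 1 array of each pair Col-0 carried Cy5 and C24 carried Cy3, and on the other C24 carried Cy5 and Col-0 carried Cy3.

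The deposited table holds 1 signed value per probe and array, with 4 decimals, which is a log ratio of the 2 accessions' DNA. The base of the logarithm of the deposited values is not given in the sources used here. They were read as log2 values without proof, so sizes are given in units of the deposited log ratio and no folds are printed. The scanner, the background correction, the normalization and any filter are likewise not given in the sources used here. The array medians over all probes in the deposited table were between -0.0014 and 0, so the authors' values had been centred. No spot intensities or background values were used, so a probe's signal over background is unknown, and the number of arrays limits the precision.

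The direction of the deposited ratio is not given either. Arrays with exchanged dyes correlated positively over probes. If the dyes were recorded rightly, the ratios had therefore been turned to run the same way before deposit, and no sign was changed here. The plan had been written for ratios of C24 over Col-0, and other departures from it are stated below. Values are reported as lying on the positive or the negative side, and which accession has more DNA signal on which side is not settled.

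The table has 18970 probes. Of these, 18931 are named by a 2-letter prefix, a plate number and a well, and they were tested. The other 39 spots, named otherwise, were left out of all tests and are described separately. The table does not pair the probes with genes or coordinates, and their identity is not given in the sources used here. The 8 gene lists and 5 chromosome regions fixed beforehand were therefore not tested, and probes are named by their plate-and-well identifiers.

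Each array was centred on the median of the 18931 probes. The arrays of a DNA pair share their extracts, so their mean, in which a dye effect cancels, was taken as 1 replicate, giving n = 2. The mean log ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. With 1 residual degree of freedom per probe, the test drew on a prior of 9.14 degrees of freedom estimated over all probes. A probe lacking a value on 1 array kept the value of the other array of its pair, and 53 probes lacked at least 1 value. For 1 probe DNA pair II had no value, and its test rests on pair I and the prior. A size rule counted probes with a mean at or beyond 1 in size, a value on all 4 arrays and the same sign on each. The dye effect, the mean of the C24-in-Cy5 arrays minus that of the Col-0-in-Cy5 arrays, divided by 2, was fitted in the same way. Named probes are the 2 highest and the 2 lowest past the size rule. These choices, and the alternatives of the closing section except where it says otherwise, were made before the data were examined. The 39 spots were set apart, and the deposited sign kept, after.

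Runs of at least 3 consecutive wells past the size rule were counted after the data had been seen. Wells were ordered by prefix, plate, row and column, a run could pass from the last well of a plate to the first of the next, and a well without a listed probe ended it. The count was set against 1000 shuffles of the probes (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). The limma step was tested on simulated data with the observed dye effects and the estimated variances of the accession fit over 18931 probes. It recovered 100 of 100 probes changed by 0.5 in size and 100 of 100 changed by 1, with 10 calls among 18731 unchanged probes. The simulated variances were drawn from the fitted prior, and the simulated dye effect cancelled within each pair by construction. The simulation therefore checks the step only under its own assumptions, and sizes under 0.5 were not simulated. Nothing in the labels says that pairs I and II came from separate cultures, so the p-values measure only the spread between these DNA pairs, which may be technical.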

Results

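The series compared the genomic DNA of 2 Arabidopsis thaliana accessions, Col-0, whose genome is the species' reference, and C24, on a tiling array of chromosome 4. It forms part of a larger study of epigenomic changes in hybrids between accessions. Arrays of this kind locate probes at which the parental genomes themselves differ in copy number or in sequence. The 4 arrays held 2 DNA pairs, I and II, each hybridised in both dye orientations. The number of probes with a value was 18970 and 18944 on the arrays of pair I with Col-0 and with C24 in Cy5, and 18959 and 18953 on those of pair II. Log ratios ran from -2.47 to 5.004 over the 4 arrays. The standard deviation over plate-and-well probes lay between 0.334 and 0.366 on each array.

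Most chromosome 4 probes gave log ratios near 0, and a minority departed far from it, mainly on the positive side. In all, 358 probes had a mean log ratio of at least 1 with a positive value on all 4 arrays. On the negative side 22 probes had a mean of -1 or below with a negative value on all 4 arrays. All 380 of these also passed the test against 0 (limma, adjusted p under 0.05, n = 2 DNA pairs). They had been picked for their size in the same values, so passing adds no separate support. The highest probe, TB24G12, had a mean log ratio of 4.62 ± 0.05 (SD, n = 2; adjusted p = 1.1e-11 in limma). The next, TB25D05, had a mean of 4.28 ± 0.19 (SD, n = 2; limma adjusted p = 3.3e-11). The lowest probe, TA30B03, had a mean of -2.26 ± 0.03 (SD, n = 2; limma adjusted p = 3.4e-10). It was followed by TA30A11 at -2.24 ± 0.13 (SD, n = 2; limma adjusted p = 9.2e-10). The deposited sign does not tell whether Col-0 or C24 gave the stronger signal at a positive probe.

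Over all 18931 plate-and-well probes, limma called 3522 at an adjusted p of 0.05, of which 2354 were on the positive and 1168 on the negative side. Most of these differences were small. Their median size was 0.31, and 2485 of them, or 70.6%, were under 0.5 in size. Unlike the size rule, the test on dye-swap means did not require the same sign on each dye orientation. Some called probes had a dye effect larger in size than their mean, so their sign turned with the dyes. Probe TA01A01, for example, had a mean of 0.426 (limma adjusted p = 0.0035) and a dye effect of 0.634. How many of the 3522 turned sign was not counted. At an adjusted p of 0.01 limma called 507 negative and 1798 positive probes. With the 4 arrays taken as independent it called 393 negative and 1584 positive probes at 0.05.

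Contrasts of the same 4 arrays that hold no accession effect gave the background for these sizes. Over the 18878 probes with a value on all arrays, 381 had an accession mean of at least 1 in size. The dye effect reached this size at 1 probe. The halved difference between DNA pairs I and II reached it at none, and the same holds for the interaction of dye and pair. At a size of 0.5 the counts were 1035 for the accession mean, 52 for the dye effect, 11 for the difference between pairs and 15 for the interaction. Above 0.5 and below -0.5 they were 874 and 161 for the accession mean and 50 and 2 for the dye effect. For pair I minus pair II they were 10 and 1, and for the interaction 0 and 15. The background was thus mostly of 1 sign in each contrast. Pooled counts do not show how it falls on the 2 sides of the accession mean. In the fit on DNA pairs limma called 3103 probes for the dye effect (adjusted p under 0.05), 862 of which were also called for the accession. With the 4 arrays taken as independent limma called 0 (2596 at an unadjusted p under 0.05), since the accession effect is then part of the spread, and with the accession mean as a further term it called 2350.

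The agreement of the arrays depended on the dyes and on the measure. Over probes, which are not independent replicates, arrays of different DNA pairs with the same dyes correlated with Pearson's r of 0.883 for C24 in Cy5 and 0.855 for Col-0 in Cy5. Their Spearman's rho was 0.616 and 0.700. The 2 arrays of a DNA pair, with dyes exchanged, had an r of 0.729 for pair I and 0.611 for pair II, and a rho of only 0.222 and 0.0899. Arrays of different pairs with exchanged dyes had an r of 0.686 and a rho of 0.213 where the C24-in-Cy5 array was of pair I. Where it was of pair II, r was 0.647 and rho 0.087. With exchanged dyes, the lower rho values were thus those with the C24-in-Cy5 array of pair II.

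The probes past the size rule were not scattered over the plates. On 123 of the 199 plates no probe passed it, and 3 plates held 98 of the 358 positive probes, or 27.4%. Plate TA62 held 45 of them among 96 probes, with a median log ratio over the plate of 0.904 ± 0.034 (SD, n = 2 DNA pairs). Plate TB25 held 40 among 95 probes. Plate TA30 held 11 of the 22 negative probes and no positive one.

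**Figure D1:**
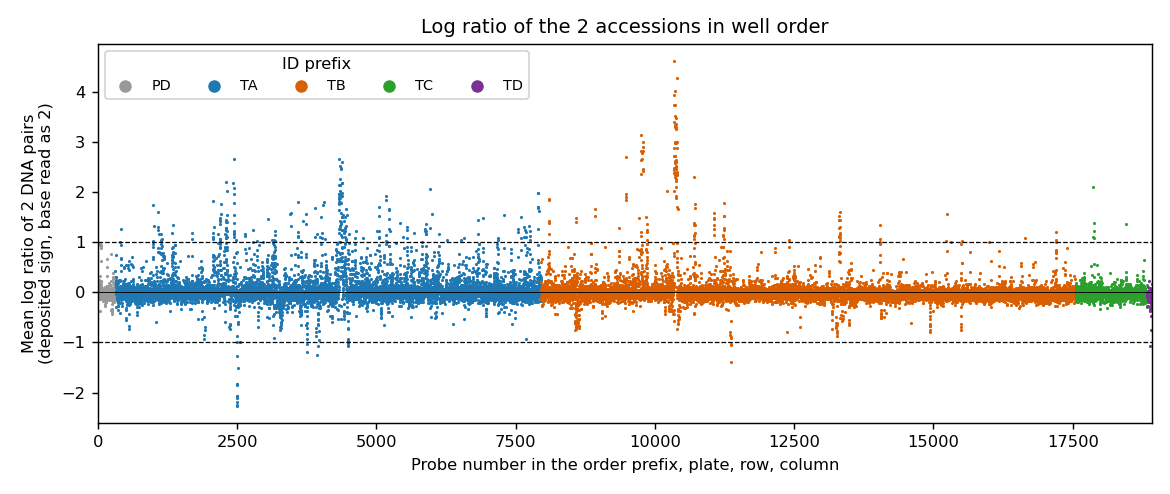
Mean log ratio of the 2 DNA pairs (vertical axis, deposited sign, base read as 2) for each plate-and-well probe in the order of prefix, plate, row and column (horizontal axis). Colours give the identifier prefix and dashed lines the size rule of 1. The highest positive probes, up to 4.62, stand in a few narrow columns, other positive probes are spread over many plates, and the lowest negative probes, down to -2.26, form a single column.

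On the positive side there were 33 runs of at least 3 consecutive wells, holding 181 of the 358 probes, and 107 probes stood in single wells. The runs had been seen before they were counted. In 1000 shuffles the highest number of runs was 2 (p = 0.001, one-sided permutation test, the smallest p that 1000 shuffles can give). The longest run had 35 wells, from the last rows of plate TB24 into plate TB25, with a mean log ratio of 2.87 ± 0.06 (SD, n = 2 DNA pairs). Across its wells the mean ranged from 1.93 to 4.62. After 1 well with a lower ratio a further run of 12 wells followed on plate TB25, with a mean of 2.64 ± 0.07 (SD, n = 2). Runs of 7 wells lay on plate TA29, in 2 places on plate TA62, and across plates TB18 and TB19. Plate TA62, whose median over all its wells was 0.904, also held shorter runs of 6, 5 and 4 wells. Runs were not counted without this plate. The shuffles moved probes between plates, so they do not tell a shift of a whole plate from a shorter stretch. The run across TB18 and TB19 had a mean of 2.72 ± 0.42 (SD, n = 2), and differed more between the DNA pairs, at 3.02 in pair I and 2.43 in pair II.

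On the negative side there was 1 run, seen before the count, and the shuffles gave none. It comprised 9 consecutive wells of plate TA30 with a mean of -1.99 ± 0.06 (SD, n = 2 DNA pairs). Its wells lay between -2.26 and -1.27. The mean was -2.03 in pair I and -1.95 in pair II. Outside this run the other 13 negative probes stood singly or in groups of 2.

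**Figure D2:**
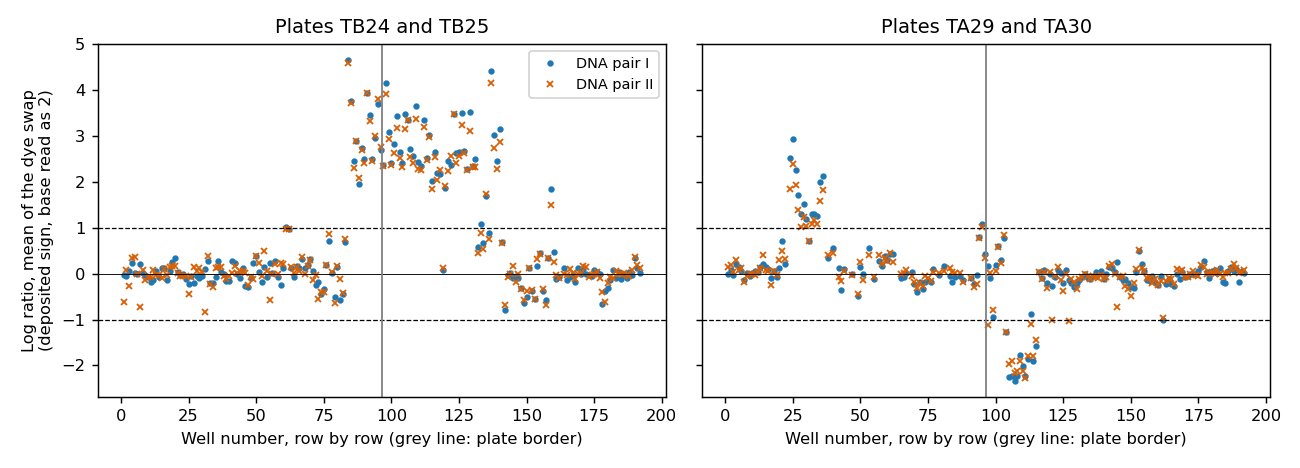
Log ratio (vertical axis, mean of each dye swap, deposited sign, base read as 2) against well number counted row by row (horizontal axis) on plates TB24 and TB25 and on plates TA29 and TA30, with DNA pair I as dots and pair II as crosses. The 35-well run at a mean of 2.87 passes the border between TB24 and TB25, and the 9-well negative run at -1.99 lies on TA30, with both pairs at similar levels.

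The 39 spots not named by plate and well were measured on the same arrays, and none of them passed the size rule. Only 380 of the 18931 plate-and-well probes passed it, so none among 39 tells little. Spots with opposite signs on the 2 orientations could not pass by the definition of the rule. Of the 39 spots, 8 bear names in common use for reporter, selection or other genes. They include GFP (green fluorescent protein), GUS (beta-glucuronidase), LUC (luciferase), and NPTII, HPH and BAR, which are antibiotic or herbicide resistance genes. The others are BT and GLOBIN. They were grouped by name after their values had been seen. Each was negative on both arrays with Col-0 in Cy5 and positive on both arrays with C24 in Cy5. GFP had a mean of -2.08 ± 0.44 (SD, n = 2) in the first orientation and 1.90 ± 0.16 (SD, n = 2) in the other. NPTII had -1.55 ± 0.02 and 1.18 ± 0.18 (SD, n = 2 each). Averaged over the 4 arrays, the 8 spots lay between -0.28 and -0.01. Of the 11 spots whose names begin with SP, 8 had opposite signs on the 2 orientations, and so had 2 of 10 with names beginning with C and 1 of 10 with names beginning with M. What these names stand for is not given in the sources used here.

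**Figure D3:**
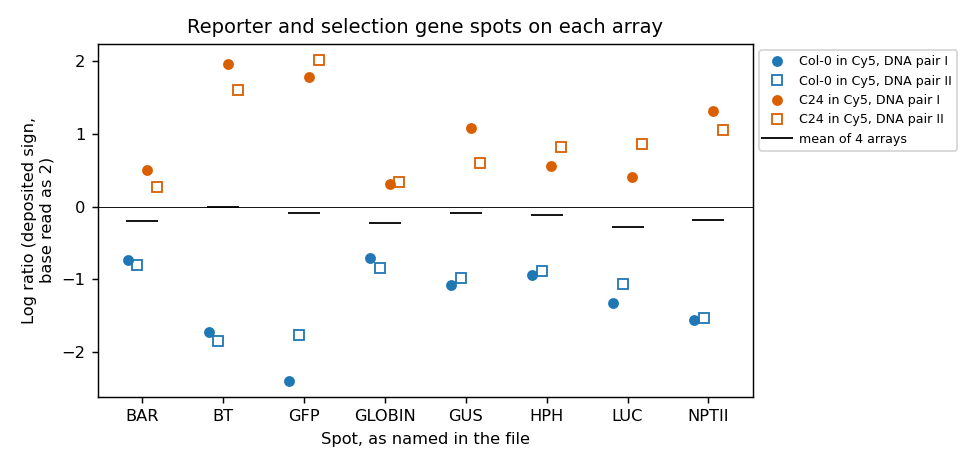
Log ratio (vertical axis, deposited sign, base read as 2) of 8 spots named for reporter, selection or other genes (horizontal axis) on each of the 4 arrays. Blue marks show arrays with Col-0 in Cy5, orange marks arrays with C24 in Cy5, and black bars the mean of the 4 arrays. The blue marks are all below 0, the orange marks all above 0, and the means lie between -0.28 and -0.01.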

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

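The test in this part was chosen after the data had been seen. The 8 spots named for reporter, selection or other genes moved in opposite directions on the 2 dye orientations. The difference C24 in Cy5 minus Col-0 in Cy5, divided by 2, was 1.99 for GFP, 1.78 for BT, 1.37 for NPTII, 0.937 for GUS, 0.913 for LUC, 0.801 for HPH, 0.578 for BAR and 0.555 for GLOBIN. With 2 arrays per orientation these differences were not tested singly. If the ratios had been turned by the recorded dyes, a wrong record in 1 orientation would turn the chromosome probes too. Among 367 probes beyond 1 in size on the Col-0-in-Cy5 arrays, the share with the same sign on the C24-in-Cy5 arrays was 0.965. That the ratios had been turned was itself inferred from agreement between the orientations. This share therefore cannot exclude a wrong record of the dyes. The central 95% of the dye effect of the plate-and-well probes ran from -0.249 to 0.247. A dye-dependent background at spots that bind little Arabidopsis DNA may account for the pattern, and it stays open because no spot intensities were used here.

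Among the 18878 plate-and-well probes with a value on every array, 4661, or 24.7%, also had opposite signs on the 2 orientations. Independent random signs would give 12.5%, a value that leaves out the shared extracts of a pair and any accession effect. Only 25 of the 4661 probes had a dye effect of at least 0.5 in size.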

How the results depend on the processing

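The 4 named probes kept their sign and an adjusted p under the threshold in limma in each of 12 other settings, with a highest adjusted p of 2.5e-06. The settings with an adjusted p of 0.01 and with an added size of at least 1 reuse the main fit. The probes had been picked as the most extreme in the same values, so their persistence adds no separate support. Leaving out 1 DNA pair left 318 to 406 positive and 25 to 27 negative probes past the size rule, 29 to 37 positive runs and 1 to 2 negative runs. Called probes numbered 360 positive and 22 negative when a size of at least 1 was also required. Negative calls fell from 1168 to 507 at an adjusted p of 0.01, and to 393 with the 4 arrays as independent, in which the dye effect enters the spread by construction. With the DNA pair as a replicate block on the 4 arrays, limma called 2675 positive and 1705 negative probes, at an estimated correlation of -0.57 within pairs, which the exchanged dyes make negative. At a size of 0.5 the size rule gave 872 positive and 150 negative probes, 88 positive and 17 negative runs, and at 1.5 it gave 155 and 10 probes. With only the Col-0-in-Cy5 arrays 42 negative probes passed, 20 of them among the 22, and the cause was not tested. The Col-0-in-Cy5 array of pair II alone had 77 probes at -1 or below, against 38 on that of pair I. The C24-in-Cy5 arrays had 26 in pair II and 27 in pair I. Runs of at least 5 wells numbered 12 on the positive side. The dye contrast called 3103 probes, and 0 when the 4 arrays were taken as independent in limma, since the accession effect is then part of the spread (2596 at an unadjusted p under 0.05), and 2350 with the accession mean as a term, a setting added after seeing the data. Centring, quantile normalization, the robust prior, missing values and the dye filter left every count computed with them within 1.5 times. Settings added after seeing the data were the dye term (2439 positive and 1248 negative calls) and the same without the Col-0-in-Cy5 array of pair II (2037 and 812, and 378 and 26 past the size rule), together with all settings for runs and prefixes. The difference between prefixes TA and TB in the share of positive probes was 1.45 percentage points, 0.896 without plate TA62, and 1.99 without plates TB24 and TB25, plates picked for their high counts in both cases, so that the direction of each move was fixed by the choice. The planned settings for gene lists, regions and runs along the chromosome were not run, because the probes were not placed on genes or coordinates. How far signal over background limits these values is unknown without spot intensities.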

Other observations

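The correlation across plate borders, the ratio of correlations for slides and the share beyond 0.5 for the spread between arrays were set out before their values were seen, and the other tests in this part, those on wells 48 apart and on runs included, were chosen after. Probe groups given by the identifier prefix differed in how many members departed. Of the 7640 probes with prefix TA, 216 were past the size rule on the positive side and 18 on the negative side, against 136 and 3 of the 9597 with prefix TB. For prefix TC it was 6 and 0 of 1282. None of the 316 PD probes passed it, and limma called 23 of them positive and 14 negative at an adjusted p of 0.05. The share called was 11.7% for PD, 26.8% for TA, 13.6% for TB, 9.44% for TC and 18.8% for TD. Over all prefixes 3522 of 18931 probes were called. Among the 96 TD probes limma called 1 positive and 17 negative, and 1, on the negative side, passed the size rule. With plates as units, the mean share of positive probes was 2.87% over 80 TA plates and 1.42% over 100 TB plates, a difference that a two-sided permutation test did not separate from chance (p = 0.074). Without plate TA62 the TA share was 2.32% and the permutation test gave p = 0.18. Without plates TB24 and TB25 the TB share was 0.882% and the permutation test gave p = 0.00041. These plates were all picked for their high counts, so neither p is independent evidence. What the prefixes stand for is not given in the sources used here.

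The runs of consecutive wells are compatible with the hypothesis that wells follow the chromosome and that the runs are stretches in which the accessions differ. Plates handled as units are argued against as a general source of the runs. Across the borders of 191 neighbouring plates Spearman's rho was 0.294 (bootstrap 95% interval 0.147 to 0.435), just short of the 0.3 set beforehand but above the 0.1 that this explanation allows, and wells 48 apart within a plate had a rho of 0.0439 against 0.346 for neighbours. Plate TA62 goes the other way, with a median of 0.904 against -0.0024 on plate TA61 and 0.179 on plate TA63. An effect of that single plate is not excluded. Defects of single slides are argued against too, since the halved difference of the DNA pairs was related between neighbours at 0.239 times the rho of the accession mean, and all 221 probes of the runs found on the arrays of pair I alone lay beyond 0.5 on the same side on those of pair II. The dye effect, too, was related between neighbouring wells (rho 0.274), so an effect of place or of probe content on the dyes is not ruled out. If the dyes were recorded rightly, such an effect would turn sign with the dyes and cancel in the accession mean. As the source of the runs it is then argued against. Of 151 probes in runs found on the Col-0-in-Cy5 arrays alone, 151 had the same sign on the C24-in-Cy5 arrays, a share of 1. Whether the wells follow the chromosome stays open, since no chromosome positions were used here.

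The tail beyond 1 in size was longer on the positive side by a factor of 16.3. Spread between arrays is argued against as its source, since the halved difference of the DNA pairs had 0.0106 times as many probes beyond 0.5 in size, and so is the centring of the arrays, since the centre would have to move by 0.5 to make the tails alike, which would put 95.4% of probes below 0, while mean and median of an array differed by at most 0.0476. The size of the factor depended on the setting, at 5.81 for a size of 0.5, 7.64 on the Col-0-in-Cy5 arrays alone, and 3.95 on the single Col-0-in-Cy5 array of pair II. If the probes were made from the sequence of 1 accession, sequence lost or altered in the other would lengthen the tail on the first one's side. Col-0 is a candidate source, being the reference accession, and positive values may then mean more signal from Col-0. This could not be tested, because neither the direction of the ratio nor the source of the probes is given.

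The Col-0-in-Cy5 array of pair II differed by at least 1 from the Col-0-in-Cy5 array of pair I at 47 probes, and it was the lower of the 2 at 46. Of these 47, 45 came from rows A, C, E or G and odd columns, which hold 25.1% of all wells. The C24-in-Cy5 arrays differed by that much at 8 probes. None of the 47 was past the size rule, and 21 were called by limma.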
